A study of Oncorhynchus kisutch with 9 samples.

How the data were processed

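Liver RNA of adult coho salmon (Oncorhynchus kisutch) was compared on spotted salmonid cDNA microarrays hybridised with Cy3- and Cy5-labelled cDNA. Per the labels, equal amounts of RNA from 5 fish were combined into 1 pool for each of 3 conditions: non-transgenic controls (C), growth hormone transgenic fish called ration-fed (R), and growth hormone transgenic fish on full ration (T). The amounts fed are not given in the sources used here. The 9 arrays form a loop of 3 comparisons, T over C, R over C and T over R. Each comparison has 3 arrays, with 1 of them in the opposite dye order to the others, and 20 ug of total RNA went into each labelling. Every array of a comparison holds the same RNA, so the 3 arrays are technical repeats of 1 replicate. There is no replicate of a condition, so no SD, standard error or p-value here covers variation between fish. These values cover differences between hybridisations of the same RNA, and on centred values the SD also includes differences between dye orders. They concern the measurement of these pools, not how fish of a condition vary.

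The deposited table holds 8736 features (spots) by 9 arrays, with no missing value. The print layout is not given in the sources used here. The spot identifiers were read as 48 blocks of 13 rows and 14 columns, and the spot pairs and the centring of print blocks rest on that reading. The labels and the table do not name a scale. The deposited values were taken as log2 ratios of the 2 channels because 2 to the power of the value was a ratio of whole numbers with a denominator of at most 1000 for 995 of 78624 values, against 11 after a small random shift. With base e the counts were 15 and 14, and with base 10 they were 50 and 45. On single arrays 86 to 134 of 8736 values were such ratios, against 0 to 3 after the shift. Whether the channels were scaled against each other for the remaining values was not settled. Array medians of the deposited log2 values ran from -1.39 to -0.586, so the values were not centred by the authors. The scanner, the image quantification, the background treatment and any filter are not given in the sources used here. Intensities were not used here, so dim and saturated spots could not be set apart, and the array number limits the precision.

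All 9 columns correlated positively as deposited (r from 0.05 to 0.836 across features), which was read as a dye trend common to all arrays. The rule fixed beforehand was that ratios follow the dyes if swapped arrays of a comparison correlate negatively as deposited. These correlations were 0.05 to 0.527, so the rule was not met. With the arrays centred and turned by their dye labels, as in the main setting, the swapped arrays correlated at -0.527 to -0.05. Once the dye trend was removed and the arrays were turned by their dye labels, the swapped arrays correlated at 0.525 to 0.728. The removal assumes that the ratios follow the dyes and itself favours such positive values. The ratios were therefore taken to follow the dyes, which was not separately shown. Which dye is the numerator is not given in the sources used here, and no named growth hormone feature was there to settle it. Sizes and counts are therefore reported without saying which pool was higher. Direction 1 and direction 2 name the opposite sides of a ratio and are used in the same sense in all 3 comparisons. If the values are Cy5 over Cy3, direction 1 is the first-named pool being higher. If they are Cy3 over Cy5, it is the second-named pool. Statements that features moved the same or opposite ways do not depend on this.

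The following was computed from the deposited values. Each array was centred on its median and turned by its dye order. The arrays of like order were averaged first and then the 2 orders, so that a feature's constant dye effect cancels. A feature was called when this dye-balanced mean was at least 1 on the log2 scale (2-fold) with the same sign on all 3 arrays. No test of a condition was made. These settings, the alternatives and 26 gene lists were fixed before the data were examined. Because the dye trend turned out to differ in strength between arrays, a further setting was added after the values were seen. In it, each array had a lowess curve (fraction 0.3, 3 iterations) on the mean of the 9 arrays subtracted. If the ratios follow the dyes, the pool differences of the loop add up to 0 in that mean, which then holds no pool difference. The curve was fitted to each array's own values, so it also takes out any pool difference that runs with that mean, by an amount that was not tested. Results with the dye trend removed are given beside the main ones. limma 3.58.1 (R 4.3.3) was fitted over the 9 arrays with 2 pool contrasts and a dye term, with Benjamini-Hochberg adjustment over all features, as an alternative. For the named genes it was fitted to the means of the 4368 spot pairs and adjusted over these. Other alternatives were a plain mean of the 3 arrays, uncentred values, equalised spread, a 1.5-fold threshold, 2-fold on each array, limma on the 3 averaged ratios, the indirect ratio through the third pool, centring within print blocks (added later), and leaving out each array. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 did the rest.

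The procedures were tested on simulated data with the real dye curves, the real spread between arrays, and 50 of the 8736 features changed at each of 4 sizes. In simulated T over C, the 2-fold rule called 50.0% of 50 features changed by exactly 1 on the log2 scale and 100% of those changed by 1.5, by 2.0 or by 3.0, with 0 calls among 8536 unchanged features. In the same simulation limma called 232 unchanged features on centred values and 12 with the dye trend removed. The simulated dye curves were those the removal had fitted to the real arrays, with independent noise added, so this comparison favours the removal. The limma counts under Results are those with the trend removed, and other limma counts are given among the alternatives.

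The platform table given for this work names 8 features of 4 genes (col1a2, pck2, pparg and tap1), each on neighbouring spots, and the other 8728 features are unnamed here. None of the 4 gene identifiers matched the coho RefSeq table (assembly Okis_V2), which holds all 4 symbols. No coordinates are given because the array has no stated build. Of the 26 lists only the one of glycolysis and gluconeogenesis had a named member, pck2. No list reached the minimum of 3 genes, so no list was tested, including those of growth hormone signalling, metallothioneins and the markers of other cell types. The rule for named genes (the 12 highest and 12 lowest called genes of each comparison) found no called gene among the 4, which are all reported. Growth hormone and metallothionein values, also planned, could not be given. The report gives 2 unnamed spot pairs in each direction, the most changed in T over C, each by the identifier of its first spot. They were chosen after their values were seen.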

Results

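Hepatic transcript ratios were measured in 3 pools of liver RNA from adult coho salmon, each made from 5 fish. Growth hormone transgenic fish carry an added growth hormone gene and grow faster than non-transgenic fish when food is not limiting. The loop of 3 comparisons asked how the liver of full-ration transgenic fish (T) differed from that of non-transgenic controls (C), how much of this was present in transgenic fish that were ration-fed (R), and how the transgenic pools differed from each other. Of 8736 features, 8 carried a gene name here, so named results cover 4 genes and the rest are counts and sizes of unnamed features. Which pool was the higher could not be settled from the deposited ratios, so differences are given as sizes, and directions 1 and 2 stand for the opposite sides of a ratio.

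Neighbouring spots in an odd and the next even column behaved as duplicates. Their dye-balanced means correlated at 0.907 in T over C, 0.803 in R over C and 0.835 in T over R, against -0.019, 0.049 and 0.039 for pairs shifted by 1 spot. The features therefore make up 4368 spot pairs. The median SD over the 3 arrays of a comparison was 0.505 (T over C), 0.444 (R over C) and 0.479 (T over R) on the log2 scale. With the dye trend removed it fell to 0.169, 0.175 and 0.177. The SD on centred values thus includes the dye trend, which the dye-balanced mean is meant to cancel. It is not the error of that mean. Over all features the centred arrays of opposite dye order did not agree, with correlations of -0.527 to -0.05 once turned. The sign was the same on all 3 arrays at 1489 (T over C), 1414 (R over C) and 1853 (T over R) of 8736 features. With the dye trend removed these counts were 4252, 3520 and 4004.

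The full-ration transgenic pool differed from the control pool by at least 2-fold, in the same sense on all 3 arrays, at 222 features (2.54%). Of these, 175 lay in direction 1 and 47 in direction 2, and the median size among them was 2.38-fold. When the dye trend was removed, 190 features passed, 117 in direction 1 and 73 in direction 2, and 153 features were called the same way in both settings. The share of calls in direction 1 was 78.8%, 61.6% with the trend removed, 57.8% with equalised spread and 94.2% without centring. Both spots of a pair were called at 88 pairs, a single spot at 46 pairs, and no pair had its spots called in opposite directions. The most changed pairs in direction 2 were those starting at spot 7011209, with a 7.15-fold difference (log2 size 2.84 ± 1.03, SD over 3 arrays), and at spot 10010303, with a 6.46-fold difference (2.69 ± 0.99). In direction 1 they were those starting at spot 1010605, at 6.05-fold (2.60 ± 0.98), and at spot 2030909, at 5.91-fold (2.56 ± 1.17). The same 4 pairs gave, with the dye trend removed, log2 sizes of 2.89 ± 0.15, 2.85 ± 0.16, 2.51 ± 0.16 and 2.54 ± 0.07. limma over the 9 arrays with the dye trend removed put 2029 features (23.2%) past an adjusted p of 0.05, 1171 in direction 1 and 858 in direction 2, a test of these pools and not of the conditions. The count rests on the 1 array of opposite dye order: without it, which leaves the dyes uncancelled, 590 features passed, 5.8% of them in direction 1, whereas with the dye trend removed leaving out any array gave 188 to 206.

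The ration-fed transgenic pool differed from the control pool at 80 features (0.92%), 58 in direction 1 and 22 in direction 2, with a median size of 2.40-fold. The count was again 80 with the dye trend removed, 49 and 31 in the 2 directions, and 70 features were shared. The largest difference was 5.48-fold. Of the 4 pairs named above, pair 10010303 differed by 5.42-fold (log2 size 2.44 ± 0.86), close to its T over C size, and pair 7011209 by 1.76-fold (0.82 ± 1.21). Pair 1010605 differed by 2.73-fold (1.45 ± 1.17) and pair 2030909 by 2.74-fold (1.45 ± 1.16). Each of these lay on the same side as in T over C. With the dye trend removed the log2 sizes were 2.555 ± 0.066 for pair 10010303 and 0.917 ± 0.087 for pair 7011209. They were 1.341 ± 0.154 for pair 1010605 and 1.358 ± 0.091 for pair 2030909. limma with the dye trend removed put 977 features (11.2%) past an adjusted p of 0.05, 449 in direction 1 and 528 in direction 2. Without the array of opposite dye order 1060 features passed, whereas with the dye trend removed leaving out any array gave 80 to 86.

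The transgenic pools, which differ in ration, differed from each other at 87 features (1.0%), 63 in direction 1 and 24 in direction 2, with a median size of 2.21-fold. The count was again 87 with the dye trend removed, split 52 and 35, and 69 features were shared. The share in direction 1 was 72.4%, 59.8% with the trend removed, 53.1% with equalised spread and 91.1% without centring. Pair 7011209 differed by 4.15-fold (log2 size 2.05 ± 0.97) on the same side as in T over C. Pair 10010303 differed by 1.33-fold (0.41 ± 0.91), below the threshold. Pair 1010605 differed by 2.30-fold (1.20 ± 0.95) and pair 2030909 by 2.13-fold (1.09 ± 1.05). With the dye trend removed the log2 sizes were 2.008 ± 0.023 for pair 7011209 and 0.458 ± 0.113 for pair 10010303. They were 1.216 ± 0.008 for pair 1010605 and 1.161 ± 0.058 for pair 2030909. limma with the dye trend removed put 1564 features (17.9%) past an adjusted p of 0.05. Without the array of opposite dye order 842 features passed, whereas with the dye trend removed leaving out any array gave 86 to 95.

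Features called in T over C were looked up in the other comparisons. Of the 222 features called in T over C, 55 (24.8%) were also called in R over C in the same direction and not in T over R. Another 43 (19.4%) were called in the same direction in T over R but not in R over C, among them 1 called in R over C in the opposite direction. A further 4 were called in the same direction in both, and 120 (54.1%) in neither. These were 57, 43, 4 and 86 of 190 when the dye trend was removed. R over C and T over R add up to T over C if the loop closes. A feature at the median called size of 2.38-fold then cannot reach 2-fold in both. The few features in both and the many in neither are thus largely set by the threshold, and do not show separate groups of features. In all, 59 features were called in the same direction in T over C and R over C, where independent lists of these lengths would share 1.28, and 1 was called in opposite directions. T over C and T over R shared 47, where independent lists would share 1.39. Both pairs of comparisons have a pool in common, whose own deviation enters both lists and cannot be measured from 1 pool, so the excess is not a measure of a shared effect. The overlap of T over C with R over C was 37 without the T over C array of opposite dye order and 111 without that of R over C.

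**Figure D1:**
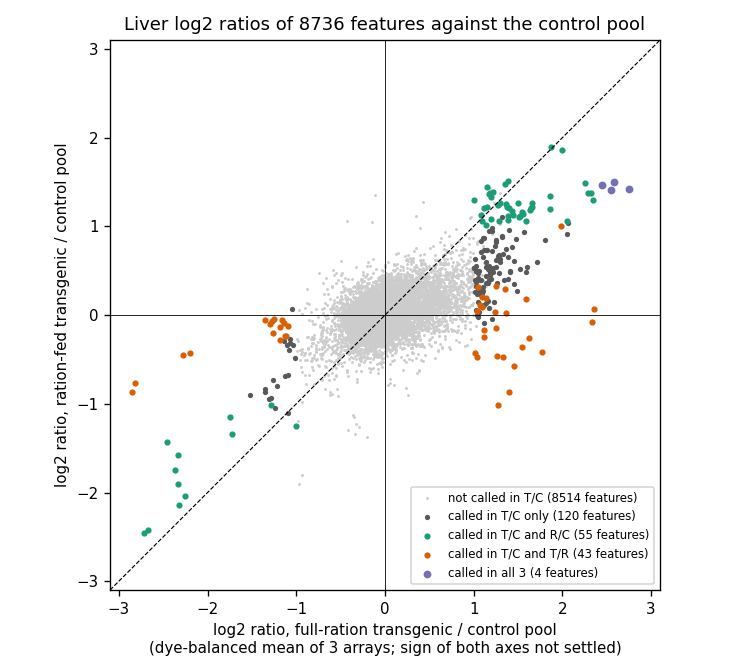
Each point is 1 of 8736 features. The x axis is its dye-balanced log2 ratio of the full-ration transgenic over the control pool and the y axis that of the ration-fed transgenic over the control pool, each from 3 arrays, with the sign of both axes not settled. The dashed line marks equal ratios. Of the 222 features called in T over C, the 55 also called in the same direction in R over C but not in T over R lie toward the dashed line, and the 43 also called in the same direction in T over R but not in R over C lie toward the horizontal axis.

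At features called in T over C the ratio of R over C had the same sign at 203 of 222 (91.4%), and its median was 47.4% of the T over C log2 ratio, with quartiles of 23.9% and 71.2%. The T over R ratio had the same sign at 208 (93.7%), with a median of 46.6% and quartiles of 23.3% and 72.5%. These features were chosen for a large T over C ratio, and array error in that ratio lowers both shares. R over C and T over R add up to T over C, and each shares a pool with it. A deviation of the shared pools alone would thus give like signs and intermediate shares. The shares are not a measure of what the ration-fed pool retained. The loop gives a check between arrays, since T over C minus R over C should equal T over R. Across all features, which are not independent replicates, these values correlated at r = 0.715 (Spearman 0.576), with a misfit SD of 0.245 on the log2 scale. The slope of T over R on that difference was 0.668. With the dye trend removed r was 0.674 (Spearman 0.513), the slope 0.622 and the misfit SD 0.244. Across the 278 features called in any comparison r was 0.959. These were chosen for large ratios on the same arrays, which widens their range and raises r, so this is no separate check. Without the T over C array of opposite dye order r over all features was 0.188, and without that of R over C it was 0.259.

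None of the 4 named genes reached 2-fold in any comparison. The largest difference among them was in col1a2, which encodes the alpha-2 chain of type I collagen, the main fibrous protein of connective tissue. It differed by 1.61-fold between the transgenic pools (log2 size 0.69 ± 0.83, SD over 3 arrays) and by 1.36-fold between T and C on the same side (0.45 ± 0.90). The centred R over C ratio lay on the opposite side with a size of 0.18 ± 1.03. Once the dye trend was removed, the T over R size of col1a2 was 0.63 ± 0.09 and the T over C size 0.28 ± 0.10, each with the same sign on all 3 arrays. The R over C size was 0.295 ± 0.388 on the opposite side, with 2 of 3 arrays on that side. limma over the 9 arrays with the trend removed gave col1a2 a T over R size of 0.61 (SE 0.10, adjusted p = 0.00021) and a T over C size of 0.32 (SE 0.10, adjusted p = 0.021). Its R over C size was 0.29 (adjusted p = 0.052). The limma adjusted p on centred values was 6.5e-06, 0.00041 and 0.34 for T over R, T over C and R over C. The centred values depended on the arrays of opposite dye order. Without that array the T over C value was -0.29 against 0.45, the R over C value 0.66 against -0.18 and the T over R value 1.38 against 0.69. With the plain mean the R over C value was 0.10, so its side was not settled on centred values. Removal of the dye trend did not settle it either, since array 1 of R over C stood at 0.14 against -0.62 and -0.35 on the others.

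For tap1, a subunit of the transporter that supplies peptides for class I major histocompatibility molecules, the T over C difference was 1.20-fold (log2 size 0.26 ± 0.18). It lay on the side opposite to that of col1a2. When the dye trend was removed it was 0.20 ± 0.31, an SD larger than the mean. limma with the dye trend removed gave tap1 a T over C size of 0.30 (SE 0.10, adjusted p = 0.033), with 2 of 3 arrays on that side, and an adjusted p of 0.0038 on centred values. Its R over C and T over R limma sizes with the trend removed, 0.11 and 0.19, did not pass (adjusted p = 0.59 and 0.20), nor did those on centred values (adjusted p = 0.47 and 0.081). The centred R over C and T over R log2 sizes were 0.15 ± 0.15 and 0.18 ± 0.43. For pck2, the mitochondrial phosphoenolpyruvate carboxykinase of gluconeogenesis, sizes were 0.06 ± 0.93 in T over C, 0.01 ± 0.86 in R over C and 0.17 ± 0.90 in T over R. Without the array of opposite dye order the centred values were -0.86 against -0.06, 0.72 against -0.01 and 0.93 against 0.17. When the dye trend was removed the pck2 sizes were 0.22 ± 0.08, 0.12 ± 0.22 and 0.12 ± 0.08, with the same sign on all 3 arrays within each comparison. In R over C, array 1 had a value of only -0.003. T over C and R over C lay on one side and T over R on the other. That is not the side of T over C minus R over C. Each of these sizes was smaller than the misfit SD of the loop over all features, 0.244 with the dye trend removed. The difference in side therefore shows no misfit particular to pck2. limma with the trend removed gave pck2 adjusted p of 0.21, 0.092 and 0.62 in the same order, none past the threshold. For pparg, a nuclear receptor of fat storage, sizes were 0.004 ± 0.070, 0.17 ± 0.42 and 0.20 ± 0.26 in the same order, and 0.03 ± 0.14, 0.15 ± 0.41 and 0.22 ± 0.17 with the trend removed. Its smallest limma adjusted p with the trend removed was 0.33, in T over R.

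**Figure D2:**
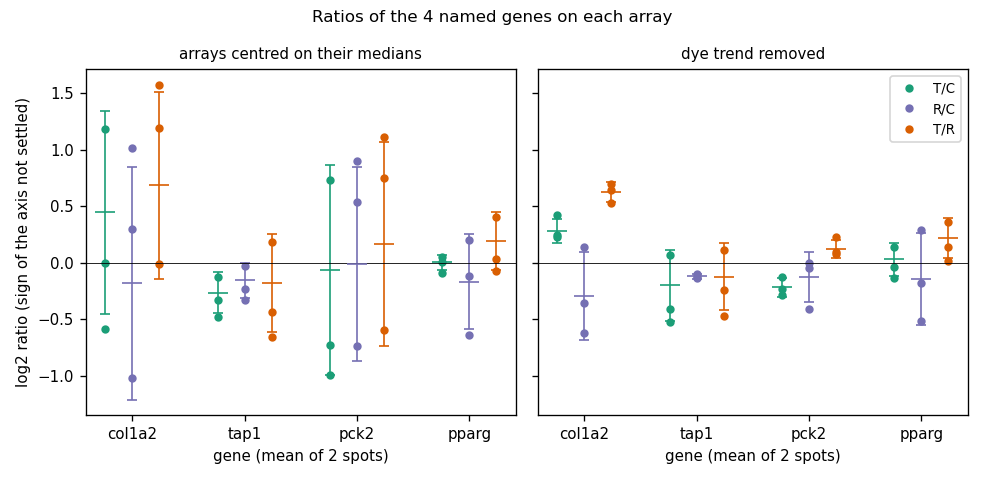
Log2 ratios of the 4 named genes, each the mean of 2 spots, in the 3 comparisons, with the sign of the axis not settled. Points are single arrays, short horizontal lines the dye-balanced mean and bars the SD over 3 arrays, which in the left panel includes the dye trend. The left panel has arrays centred on their medians and the right panel the dye trend removed, where the T over R ratio of col1a2 stands at 0.63 ± 0.09.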

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

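The comparison in this part was chosen after the values were seen. At 2 features, the spots lay on one side on all 3 arrays of T over C and on the other side on all 3 arrays of R over C, with both differences at least 1.5-fold. The 2 features, unnamed here, form a single spot pair, and both were called in T over R. When the dye trend was removed there were 5 such features, 4 of them called in T over R. The difference between the comparisons was not tested for these features.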

How the results depend on the processing

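Tests with the dye trend removed (calls, limma, arrays left out) and with centred print blocks were chosen after the values were seen. Counts below are for T over C, R over C and T over R in that order, against 222, 80 and 87. The 1.5-fold threshold gave 552, 197 and 369, and 2-fold on each array 35, 7 and 12. limma gave 2029, 977 and 1564 with the dye trend removed, 2508, 941 and 1709 over the 9 arrays on centred values, and 2692, 933 and 1648 on the 3 averaged ratios. Each limma count includes smaller differences, and with a 2-fold limit limma gave 183, 77 and 80 with the dye trend removed and 250, 86 and 87 on centred values. Uncentred values gave 465 in T over C, where they moved the median of all features by 0.235. The plain mean, which leaves dye uncancelled, gave 158 in T over R. Leaving out 1 array gave 211 to 590, 80 to 1060 and 89 to 842, each highest without the array of opposite dye order. Once the dye trend was removed these ranges were 188 to 206, 80 to 86 and 86 to 95. Equalised spread, print blocks and the indirect ratio stayed within 1.5 times the main counts, and requiring values on all 9 arrays changed nothing because none was missing. The overlap of T over C and R over C, 59 features, was 125 at 1.5-fold, 628 by limma with the dye trend removed and 628 by limma on centred values, and 37 to 111 with 1 array left out. The loop correlation of 0.715 was 0.103 with plain means, 0.959 over called features (chosen for large ratios on the same arrays) and 0.188 to 0.709 with 1 array left out. The share of T over C calls in direction 1, 78.8%, was 94.2% uncentred, 54.9% with plain means, 57.8% with equalised spread and 61.6% with the dye trend removed. For R over C it was 72.5%, then 75.6%, 84.0%, 69.0% and 61.2%, and for T over R 72.4%, then 91.1%, 94.3%, 53.1% and 59.8%. Of 84 values of the 4 genes under alternatives, 16 lay on the other side of 0 from the main value, 9 of them with 1 array left out and 0 with the dye trend removed. No paired analysis was possible because the array numbers only name hybridisations of the same pools. The filter on dim spots was not run for want of intensities, and the list alternatives because no list could be tested. Signal over background is unknown, and ratios of dim spots are compressed by an unknown amount if background was not subtracted.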

Other observations

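The tests of the imbalance of directions and of turned arrays were chosen after the result was seen, and the bounds for the test of shares were written before its result, but after single features had been seen to differ. Features called in T over C varied widely in the size of their R over C difference relative to T over C. For spot pair 10010303 the sizes were close (log2 size 2.44 in R over C against 2.69 in T over C). For pair 7011209 they were far apart (0.82 against 2.84). Over the 88 spot pairs with both spots called in T over C, the common share from a line through 0 was 50.2% in R over C and 46.2% in T over R. Intermediate common shares can arise from a deviation of the shared pools alone.

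A candidate explanation is that the ration-fed pool is a uniformly weaker copy of the full-ration pool, with array error around 1 common share. The deviations from the common share would then be noise of different arrays, and their correlation between R over C and T over R would be 0 or above. It was -0.94 over the 88 pairs, and -0.939 over 82 pairs with the dye trend removed, which argues against array error and against the dye trend as the source of the spread in shares. Each pool is a single one, so a deviation of the R, T or C pool from other fish of its condition, from an unusual fish or its RNA, would also give a negative value and stays open. A hypothesis for replicated pools is that part of the hepatic difference of transgenic fish depends on ration and another part does not, which was not tested here.

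More T over C calls lay in direction 1 (175) than in direction 2 (47). Whether dye trend left in the centred values may be the whole cause stays open. After removal of the trend, 59.8% of the 82 spot pairs called lay in direction 1, with an exact 95% interval of 48.3% to 70.4% that includes an equal split but is wide. Over the 1251 pairs past limma's adjusted p of 0.05, a wider set with smaller differences, 56.1% did (interval 53.3% to 58.9%, taking pairs as independent). The removal can also take out pool differences that run with the dye trend. An excess of biological origin was not tested.

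Whether noise between hybridisations, with no difference between the pools, could give the T over C calls was examined by turning arrays. After removal of the dye trend, turning the sign of any 1 array of T over C left 0 calls against 190. Turning array 1 gives the pattern that follows the dyes, which the removal itself largely empties. Arrays 2 and 3 have the same dye order. Turning either one therefore only asks whether these arrays agree, which a dye effect would also give. The 0 calls argue against noise that differs between arrays 2 and 3, but cannot tell a pool difference from a dye effect. On centred values turning array 2 gave 58 calls and turning array 3 gave 0, against 222. With the trend left in, the 3 arrays allow 4 sign patterns, too few for a share under 0.05. As many calls as the real count were given by 1 of the 4 in T over C (222, highest other 166), 2 of the 4 in R over C (80, highest other 390) and 1 of the 4 in T over R (87, highest other 24), the real pattern included. In each comparison the highest other pattern was the one that follows the dyes, and in R over C its 390 calls point to the dye structure of the arrays. After removal of the trend that pattern gave 0 calls in R over C against 80. The removal takes out what the arrays share in dye order, so this drop was largely fixed in advance and is no evidence for the real pattern.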
